A study of Mus musculus with 16 samples.

How the data were processed

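The samples were 16 RNA libraries of bone marrow-derived macrophages from C57BL/6J mice. Per the labels, marrow cells were grown with macrophage colony-stimulating factor, kept in medium with or without serine, and treated or not with LPS at 100 ng/mL, with RNA taken 4 h later. Each of the 4 groups had 4 libraries, and each library carries a replicate number in its title. The labels do not say whether the 4 replicates are separate animals or parallel cultures, so the p-values measure the spread between these libraries.

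The read counts per Ensembl gene were made by the authors and deposited as whole numbers for 43430 genes, one column per library. Per the submitters' processing notes, Trimmomatic 0.33, STAR, SAMtools, HTSeq and edgeR and the mm10 build were used, with no role or order given. The deposited tables of the authors also give log2 fold changes between groups, whose scaling is not stated, and adjusted p values, beside columns of a likelihood ratio test. Gene lengths and the authors' marks of genes called higher or lower were taken as deposited. The highest adjusted p of a gene they marked lies between 0.00706 and 0.00999 over the 5 tables. FPKM values and normalized counts deposited for the same libraries were not used, and 24 further per-sample columns of the count table were left out of every step. The library kit does not mark the strand, so reads from overlapping genes on opposite strands, and from close copies of a gene, are not told apart.

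Gene counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with low counts were removed with the default filter of edgeR, which left 11004 genes, and libraries were scaled by TMM. A robust quasi-likelihood model with a mean for each of the 4 groups was fitted to all 16 libraries. It gave 5 comparisons: LPS with serine, LPS without serine, serine withdrawal in untreated cells, serine withdrawal in LPS-treated cells, and the difference between the 2 withdrawals. Tests are two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 11004 genes of each comparison, and the threshold was an adjusted p of 0.05. The common dispersion was 0.0438, a biological coefficient of variation of 20.9%, and 0.02 or 14.1% without replicate 4 of the untreated cells without serine. Total counts ranged from 5760734 to 7845261 per library in untreated cells with serine, from 2871477 to 10043362 without serine, and from 6240112 to 8092528 and from 6573849 to 7892215 in LPS-treated cells with and without it. A fold change against a group with no counts is given as a lower bound from a floor of 3 counts over the group, and a ratio with 1 to 3 counts in a group with a 95% counting interval. Such floors and intervals cover counting error only.

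Replicate numbers were checked as a possible pairing. Deviations of same-numbered libraries from their group means correlated across genes between the compared groups at 0.217 to 0.415 and 0.125 to 0.397 in the LPS comparisons and at 0.185 to 0.609 and 0.333 to 0.66 in the withdrawals, and those of differently numbered libraries at -0.373 to 0.141. A value over 0.1 for each pair was the criterion, which the 4 comparisons of 2 groups met, so the numbers pair the samples there. Of the 24 pairs over all groups 23 met it, and the block changed no gene call in the difference between the withdrawals. Replicate 1 of each group had no count of Xist and 1184 to 2391 counts of Y-linked genes, while the other 12 libraries had 351 to 1477 counts of Xist and at most 1 of Y-linked genes. Replicate 1 was therefore male and the other 12 libraries female, so sex cannot be told apart from replicate 1. A block for the replicate number was an alternative to the unpaired model, which stayed the one reported because it was chosen before the data were examined. The unpaired model ignores the pairing that the check found. A withdrawal result that misses its threshold is therefore read beside the block result. None of the 120 pairs of libraries was a copy, the lowest chi-square per degree of freedom being 2.04 over genes with a mean of at least 10 counts.

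Gene lists, 34 in all, were written before the data were examined, and the 30 with at least 3 tested members were tested with camera of limma at a preset correlation of 0.01. With an estimated correlation the calls of cytokines, chemokines and antimicrobial effectors held in both LPS comparisons, and no other list call held in any comparison. A count of members is given over all genes tested and adjusted over the list alone. The overall LPS response was summarised per library as the median centred log2 CPM of genes with a mean LPS effect of at least 1 (log2) in either direction, and compared with an exact permutation test of 70 arrangements, or 16 with signs exchanged within replicate numbers, whose smallest p is 0.125. Levels on the log2 scale use a prior count of 2.

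Genes were named by a rule set before the data were examined. It took 9 genes in every comparison (Il1b, Il1a, Il6, Tnf, Phgdh, Psat1, Psph, Shmt2 and Mthfd2). It took the 8 rising and 8 falling genes with the largest changes past the threshold, a mean of at least 5 CPM in the higher group and no overlap between the libraries of the compared groups, without predicted genes and pseudogenes. From each list it took up to 4 members past the threshold with the smallest adjusted p, or, when fewer than 2 passed, the 2 with the smallest p as values. After the data were seen the same rule was applied to the block model for the withdrawals, and the text names a shorter choice of all these genes. Some genes that the rule names are not reported here. Il6 is left out of the difference between the withdrawals, because it had no count in untreated cells.

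The alternatives set before the data were examined were RLE size factors, no filter and a stricter filter on low counts, the Wald test of DESeq2 1.42.0, the replicate block, the 8 libraries of the compared groups alone, each library of those groups left out in turn, and an estimated correlation for the lists. Alternatives added after seeing the data were total-count scaling, the block without replicate 4 of the untreated cells without serine, the block on the 8 libraries alone, the lists without that library or with the block and an estimated correlation, the lists without members at the floor (at most 3 counts over a compared group) in the comparisons that rest on untreated levels, and leaving out each library of the groups not compared.

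The methods were tested on simulated data. Each gene had the same spread in every library, estimated from these libraries with the block, and a replicate effect of a set size was added. The rates below therefore do not cover a library with a wider spread of its own, and the simulated gain from the block depends on the set size. For serine withdrawal with LPS, edgeR recovered 11.1% of genes changed 1.5-fold and 69.1% of those changed 2-fold, and 27.3% and 73.2% with the block. False calls were 5.81% of its calls, 6.25% with the block and 8.7% with DESeq2. With the spread seen without replicate 4 of the untreated cells without serine it recovered 43% and 85.7%, or 65% and 87.8% with the block, with 1.45% and 7.14% of the calls false. A list of 25 genes shifted by 0.5 (log2) gave p = 1.8e-19 with the preset and 3.33e-07 with an estimated correlation in camera, and 0 of 20 unshifted lists fell under an unadjusted p of 0.05. The simulated genes varied independently of each other, so this does not show how the list tests hold for correlated genes. Other divisions of the real libraries, given below, had up to 15 lists past the threshold. The division with 15 set whole replicates against whole replicates, so differences between replicates enter it. Such counts are therefore not a rate of chance passes.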

Results

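RNA sequencing measured gene expression in bone marrow-derived macrophages, phagocytes that grow out of mouse bone marrow in the presence of macrophage colony-stimulating factor. The cells were kept in medium with or without serine, and with or without lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria that switches on inflammatory genes through Toll-like receptor signalling. The title of the series ties serine metabolism to the production of IL-1β, the cytokine encoded by Il1b. Each of the 4 combinations had 4 libraries, LPS was used at 100 ng/mL, and RNA was taken 4 h after it. Total counts of replicates 1 to 4 were 7845261, 7678780, 6403847 and 5760734 with serine and no LPS, and 10043362, 7949029, 6287007 and 2871477 without serine or LPS. With LPS they were 8092528, 6732783, 7450038 and 6240112 in the presence of serine and 7892215, 6865832, 6801410 and 6573849 in its absence. Replicate 4 of the untreated cells without serine had the lowest total, 12900 detected genes against 14997 to 16031 in the rest of its group, and 23.1% of its counts in its top 20 genes against 14.6% to 17.0%. Levels are given as CPM, counts scaled to the TMM-adjusted size of each library, as mean ± SD over the 4 libraries of a group, and changes as log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p. Coordinates are those of whole genes in mm10.

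The summed level of 14 macrophage marker genes was 22200 ± 2610 CPM in untreated cells with serine, 22800 ± 5750 without serine, 27500 ± 3530 with serine and LPS and 25600 ± 3220 with LPS and no serine. Scaled to total counts without TMM factors the same sums were 27800 ± 3030, 26900 ± 3910, 22500 ± 2080 and 20600 ± 1870 CPM, so whether they rise or fall with LPS depends on the scaling. Neutrophil markers summed to 53.1 ± 49.3, 65.2 ± 62.2, 54.1 ± 41.2 and 48.7 ± 35.9 CPM (TMM-adjusted) in the same order of groups, and dendritic cell markers to 242 ± 121, 252 ± 105, 430 ± 145 and 428 ± 126 CPM. Stromal markers summed to 19.4 ± 12.9, 18.9 ± 15.2, 46.7 ± 14 and 35.5 ± 18.8 CPM, and B and plasma cell markers to at most 6.12 ± 3.06 CPM. Mast cell and basophil markers, which include Hdc, summed to 3.13 ± 1.05, 3.91 ± 2.65, 25.7 ± 3.45 and 18.9 ± 1.82 CPM. T and NK cell markers summed to 0.329 ± 0.158, 0.278 ± 0.0634, 3.33 ± 1.97 and 3.55 ± 1.60 CPM.

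**Figure D1:**
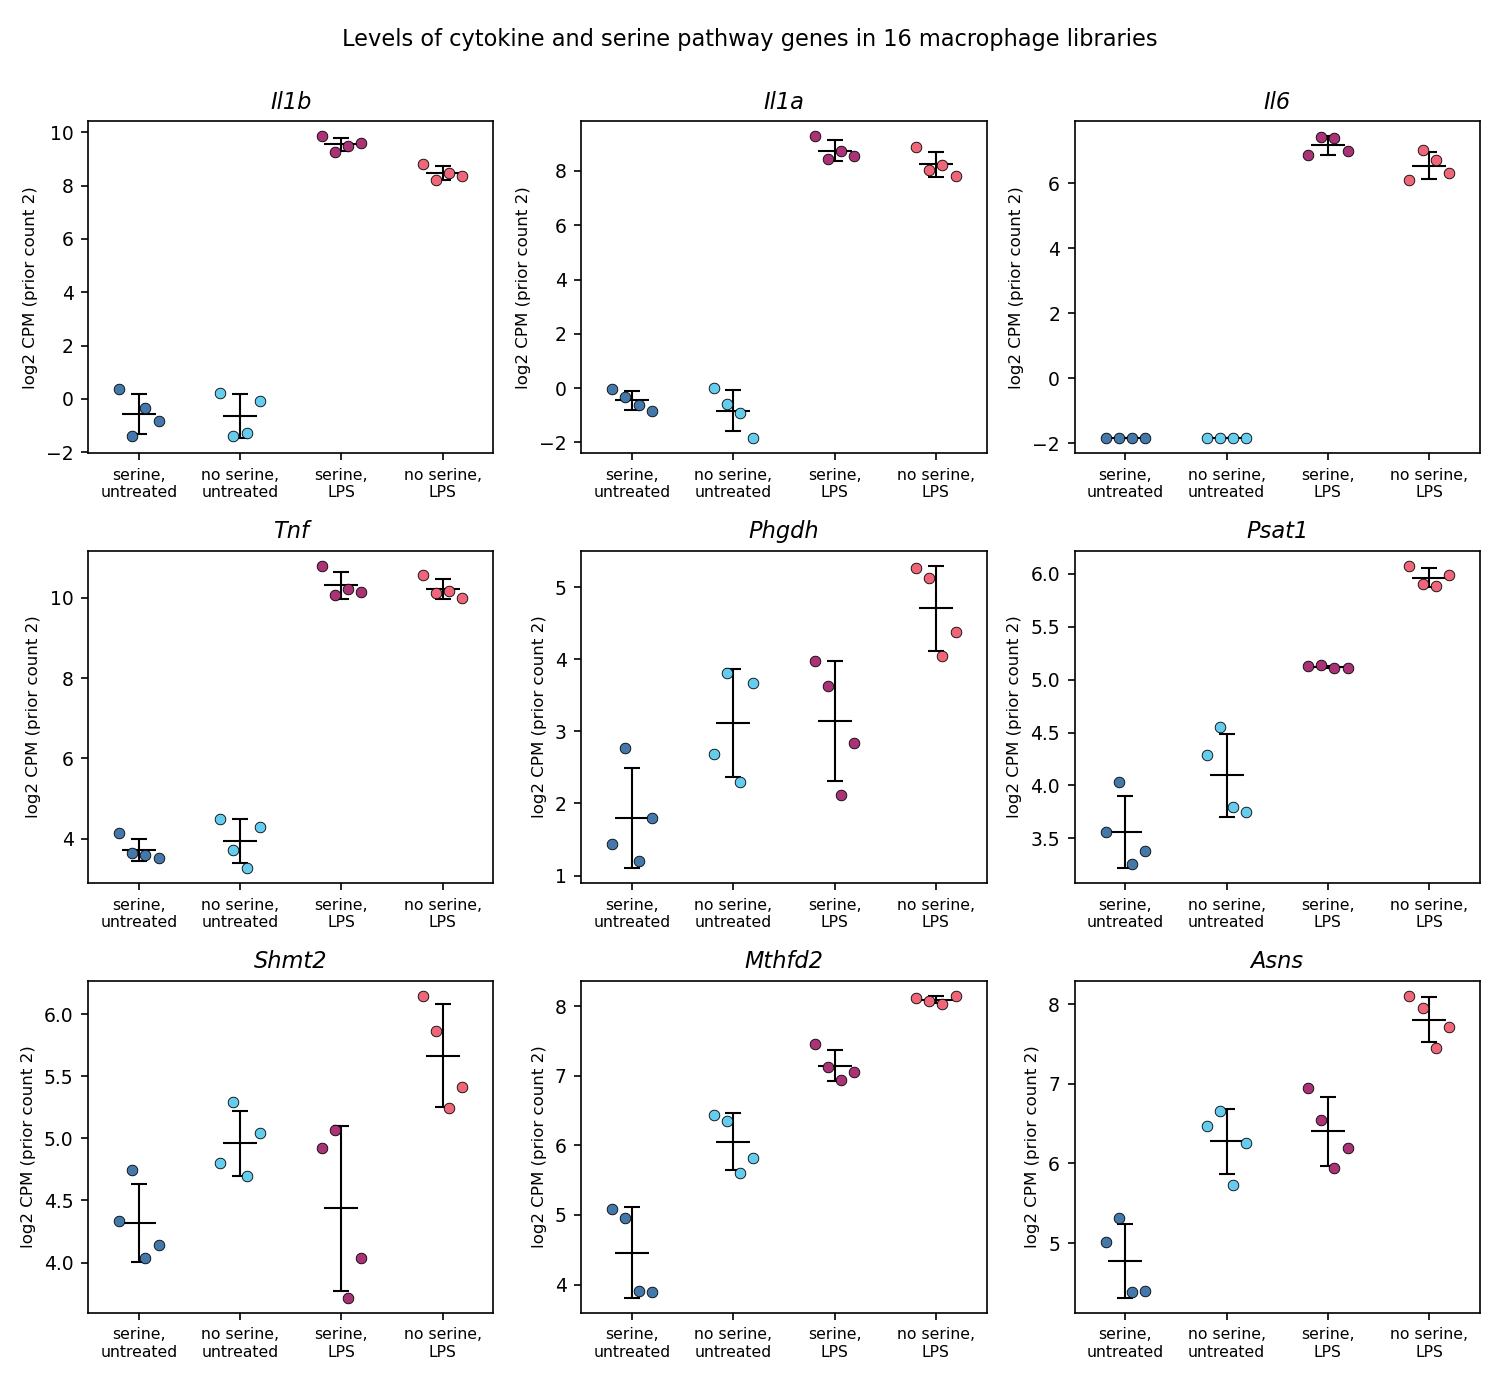
Level of 9 genes in each of the 16 libraries, as log2 CPM with a prior count of 2 on the vertical axis and the 4 groups along the horizontal axis; each point is a library, horizontal bars are group means and error bars the SD (n = 4). Il1b averaged 755 CPM with serine and LPS and 357 CPM with LPS and no serine, while Mthfd2 averaged 143 and 273 CPM in the same groups.

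The first comparison asked what LPS did to macrophages in medium with serine. Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139, minus strand) rose from 0.473 ± 0.394 to 755 ± 130 CPM, a log2 fold change of 10.55 ± 0.42 (edgeR adjusted p = 7.91e-12). Its neighbour Il1a (chromosome 2, 129299610 to 129309972, minus strand) rose by 9.78 ± 0.39, from 0.469 ± 0.186 to 442 ± 125 CPM. Tnf (chromosome 17, 35199381 to 35202007, minus strand), which encodes tumour necrosis factor, rose by 6.62 ± 0.30, from 13.1 ± 2.83 to 1290 ± 323 CPM. Il6 (chromosome 5, 30013161 to 30019968, plus strand) had no count in the untreated libraries and 145 ± 27.9 CPM with LPS, at least 1670-fold higher against a floor of 3 counts over the untreated group. Il12b, the p40 subunit of interleukin-12, was at least 1320-fold higher on the same floor. Nos2 (chromosome 11, 78920787 to 78960254, plus strand), the inducible nitric oxide synthase, went from 2 counts over the untreated group to 1090 ± 391 CPM, a ratio of 18400 with a 95% counting interval of 5100 to 152000. Ch25h (chromosome 19, 34473786 to 34475135, minus strand), cholesterol 25-hydroxylase, also had 2 counts in untreated cells and a ratio of 6890 (1910 to 56900). Of the genes that fell, the cannabinoid receptor gene Cnr2 had 3 counts with LPS and was lower by a factor of 358 (122 to 1740), the pro-apoptotic gene Bmf changed by -6.21 ± 0.31 and Zfp395 by -5.86 ± 0.27.

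Inflammatory gene groups rose together in this comparison. Of 17 tested cytokine genes 16 rose over all genes and 16 adjusted over the list alone, with a median of 5.91, or 5.71 with the 3 members that had no count in untreated cells set at their bound (camera adjusted p = 9.5e-12). Of 16 chemokine genes 15 rose, 16 adjusted over the list alone, among them Ccl3 by 8.40 ± 0.22 and Ccl4 by 9.59 ± 0.36, with a list median of 8.38, or 8.24 with 2 members at their bound (adjusted p = 2.19e-12). The 24 genes of the NF-kB pathway and its feedback all rose (median 3.26), with Ptgs2, the inducible cyclooxygenase, at 9.86 ± 0.39, Cd40 at 8.51 ± 0.27, Socs3 at 7.83 ± 0.22 and Nfkb1 at 3.36 ± 0.12. That list's test gave adjusted p = 7.14e-17, and over 6 alternatives it ran from 7.76e-17 to adjusted p = 0.119 with an estimated correlation. The 29 interferon-stimulated genes all rose as well (median 5.21), with the antiviral genes Rsad2 at 8.85 ± 0.56, Mx2 at 7.19 ± 0.38 and Ifih1 at 5.49 ± 0.32. Their test gave adjusted p = 1.07e-16, and over 6 alternatives from 1.84e-16 to adjusted p = 0.37 with an estimated correlation. Antimicrobial and immunometabolic effectors rose in 10 of 13 cases (adjusted p = 3.76e-05). Inflammasome genes went both ways, 7 higher and 3 lower of 14, and the list missed the threshold (adjusted p = 0.0577), while its sensor Nlrp3 rose by 5.50 ± 0.30.

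Metabolic and cell cycle genes went both ways. Psat1 (chromosome 19, 15904678 to 15947337, minus strand), the aminotransferase of serine synthesis, rose by 1.55 ± 0.18 from 11.8 ± 3.01 to 34.6 ± 0.277 CPM. Phgdh (chromosome 3, 98313170 to 98339990, minus strand), the first enzyme, rose by 1.43 ± 0.48 (adjusted p = 0.0184). Phgdh missed the threshold when replicate 1 or 3 of the untreated cells or replicate 1 of the LPS-treated cells with serine was left out, at 1.27, 1.24 and 1.09, and with total-count scaling, at 0.82 (adjusted p = 0.137). The phosphatase gene Psph (chromosome 5, 129765558 to 129787252, minus strand) did not pass, at -0.19 ± 0.36 (0.01 and 0.02 without replicates 3 and 4 with LPS), and the 3 genes as a list gave adjusted p = 0.528. In the folate cycle, the mitochondrial dehydrogenase gene Mthfd2 (chromosome 6, 83305691 to 83317606, minus strand) rose by 2.60 ± 0.26 and the cytosolic Mthfd1 fell by 1.29 on the log2 scale. The mitochondrial serine hydroxymethyltransferase gene Shmt2 (chromosome 10, 127517123 to 127522444, minus strand) stood at 0.21 ± 0.28, at -0.40 with total-count scaling and at -0.02 without replicate 2 with serine and LPS. The list of targets of ATF4, a transcription factor of the amino acid response, had 13 members higher and 3 lower of 27 (16 and 3 adjusted over the list alone). It was led by the cystine transporter gene Slc7a11 at 4.93 ± 0.43 and the stress gene Nupr1 at 3.83 ± 0.42, and the list passed (adjusted p = 0.0152, from 0.00217 to adjusted p = 0.846 with an estimated correlation). Glucose transporter Slc2a1 and the glycolytic regulator Pfkfb3 rose by 1.55 ± 0.18 and 3.77 ± 0.29, with 7 higher and 2 lower of 24 in the glycolysis list (adjusted p = 0.346). DNA replication genes were lower in 9 of 19 cases and higher in 1 (10 and 1 adjusted over the list alone), including Mcm2 at -1.73 ± 0.25, Mcm4 at -0.94 ± 0.13 and E2f1 at -1.40 ± 0.17. Their list gave adjusted p = 0.0249, and over 6 alternatives from 0.0104 to adjusted p = 0.687 with an estimated correlation. Sesn1 fell by 5.37 on the log2 scale in a p53 target list that split into 5 higher and 5 lower of 14 (adjusted p = 0.844). Of 14 macrophage markers Cx3cr1 and Ccr2, which encode chemokine receptors of monocytes, fell by 2.15 and 1.36 on the log2 scale. The summed level of the 14 went from 22200 ± 2610 to 27500 ± 3530 CPM (TMM-adjusted), and the other way when scaled to total counts. Hdc, histidine decarboxylase, rose by 7.21 ± 0.44, from 0.127 ± 0.153 to 23.6 ± 3.75 CPM.

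In all, 3041 genes were higher and 3098 lower with LPS of 11004 tested. Total-count scaling, which moved the median of all genes by -0.62 (log2), gave 1666 higher and 6407 lower, so that the share of higher calls went from 49.5% to 20.6%.

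The same comparison in medium without serine asked how LPS acted when the amino acid was withheld. Il1b rose by 9.60 ± 0.42, from 0.445 ± 0.391 to 357 ± 64.6 CPM (edgeR adjusted p = 2.33e-11), Il1a by 9.43 ± 0.40, to 315 ± 109 CPM, and Tnf by 6.25 ± 0.30, to 1200 ± 222 CPM. Il6, with no count before LPS, reached 95 ± 27.2 CPM, at least 1050-fold higher, and Il12b was at least 735-fold higher on the same floor. Nos2 reached 1020 ± 441 CPM from 1 count, a ratio of 32800 (5890 to 1300000), and Ch25h reached 214 ± 64.5 CPM from 3 counts, a ratio of 2340 (800 to 11300). The chemokine gene Cxcl10 and the guanylate-binding protein gene Gbp2b rose by 10.27 ± 0.58 and 10.18 ± 0.48, while Sox4, a developmental transcription factor, Cnr2 and Zfp395 changed by -6.56 ± 0.45, -6.51 ± 0.34 and -5.55 ± 0.27. Cytokine genes rose in 16 of 17 cases (median 5.82, or 5.38 with 3 members at their bound, adjusted p = 4.52e-11) and chemokine genes in 15 of 16 (median 7.86, adjusted p = 1.37e-11). All 24 NF-kB genes rose, including Ptgs2 by 9.65 ± 0.39, Cd40 by 7.82 ± 0.26 and Socs3 by 7.59 ± 0.21 (adjusted p = 7.52e-17). All 29 interferon-stimulated genes rose, including Rsad2 by 8.78 ± 0.55 and Mx2 by 6.87 ± 0.37 (adjusted p = 7.52e-17). Over 6 alternatives the test of NF-kB genes ran from 9.17e-17 to adjusted p = 0.121 with an estimated correlation, and that of interferon-stimulated genes from 1.22e-16 to adjusted p = 0.364 with an estimated correlation. Antimicrobial and immunometabolic effectors rose in 9 of 13 cases (adjusted p = 4.1e-05). Inflammasome genes were higher in 8 of 14 cases and lower in 3, and DNA replication genes lower in 9 of 19 and higher in 1 (adjusted p = 0.0458 and 0.0482, and adjusted p = 0.71 for both with an estimated correlation). Both of these lists missed the threshold without replicate 4 of the untreated cells without serine (adjusted p = 0.0765 and 0.0758), and over 6 alternatives they ranged from 0.0455 to 0.71 and from 0.0246 to 0.71.

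Of the genes of serine synthesis and the folate cycle, Psat1 went from 17.3 ± 4.80 to 62.2 ± 3.81 CPM (1.82 ± 0.18), Phgdh from 9.25 ± 4.54 to 27.4 ± 10.7 CPM (1.61 ± 0.44), Mthfd2 from 68.0 ± 18.7 to 273 ± 9.40 CPM (2 ± 0.26) and Shmt2 from 31.2 ± 5.91 to 52.1 ± 15.1 CPM (0.74 ± 0.28, adjusted p = 0.0306). Shmt2 missed the threshold without replicates 1 or 3 of the untreated cells without serine (0.69 and 0.66) and without replicates 1 or 2 with LPS and no serine (0.56 and 0.69), and with total-count scaling it stood at 0.18 (adjusted p = 0.59). Psph stood at 0.47 ± 0.34 and at -0.10 with total-count scaling, and the 3 serine synthesis genes gave adjusted p = 0.253 as a list. ATF4 targets were higher in 18 of 27 cases and lower in 1 (18 and 1 adjusted over the list alone). Slc7a11 among them rose by 4.41 ± 0.42, and the list gave adjusted p = 0.00203 (from 0.000109 to adjusted p = 0.71 with an estimated correlation). Complex I genes were lower in 12 of 25 cases (9 adjusted over the list alone) with a median of -0.673, and as a list stood at adjusted p = 0.102. When replicate 4 of the untreated cells without serine was left out under a replicate block, 9 were lower and 3 higher, with a median of -0.129. In this medium 2984 genes were higher and 3266 lower with LPS of 11004. Total-count scaling moved the median by -0.58 and gave 1686 higher and 6566 lower, a share of 20.4% higher against 47.7%.

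Serine withdrawal in untreated cells asked what the absence of serine did without an inflammatory stimulus. The gene list with the smallest p was that of the amino acid response, in which ATF4 raises amino acid synthesis and transport. Asns (chromosome 6, 7675169 to 7693254, minus strand), asparagine synthetase, averaged 28.2 ± 9.19 CPM with serine and 79.4 ± 20.6 CPM without it, Mthfd2 23.4 ± 10.2 and 68.0 ± 18.7 CPM, Atf4 itself 151 ± 32.9 and 295 ± 56.4 CPM, and Chac1, a glutathione-degrading enzyme, 1.42 ± 0.83 and 8.22 ± 3.97 CPM. Their log2 fold changes were 1.49 ± 0.26, 1.54 ± 0.26, 0.96 ± 0.19 and 2.52 ± 0.49, higher in 4 of 4 replicate pairs, and missed the threshold over all genes (edgeR adjusted p = 0.121, 0.117, 0.207 and 0.207). Of 27 ATF4 targets 0 passed over all genes and 17 adjusted over the list alone, all of them higher, and the list median was 0.843. The list gave camera adjusted p = 2.84e-19, and over 6 alternatives from 3.64e-33 to adjusted p = 0.223 with an estimated correlation. Among 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 8 were higher adjusted over the list alone and 0 over all genes, with Cars at 1.08 ± 0.18 and Yars at 1.12 ± 0.24. That list had a median of 0.428 (adjusted p = 5.68e-09, from 5.59e-14 to adjusted p = 0.223 with an estimated correlation). With the replicate block beside an estimated correlation both lists passed (adjusted p = 0.00172 and 0.00662).

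With the replicate number as a block, which pairs the libraries, 9 genes rose and 0 fell. On the 8 untreated libraries alone the block called 0 genes, with 267 at an unadjusted p under 0.05. The 9 were Asns (1.5 ± 0.13), Cars (1.09 ± 0.11), Chac1 (2.52 ± 0.29), Mthfd2 (1.56 ± 0.19), the pseudokinase gene Trib3 (1.48 ± 0.20), Atf4 (0.97 ± 0.13), the mitochondrial phosphoenolpyruvate carboxykinase gene Pck2 (1.04 ± 0.17), the cationic amino acid transporter gene Slc7a1 (1.29 ± 0.19) and Jdp2 (0.81 ± 0.12), the last 2 chosen after their values were seen. Block adjusted p values of these genes ran from 0.000378 for Asns to 0.0393 for Pck2, and over the 17 alternatives of each gene the adjusted p ranged from 5.25e-05 to 0.915 for Asns and from 0.000273 to 0.936 for Pck2. The fold change of Jdp2 stood at 0.45 without replicate 1 of the untreated cells without serine and at 1.21 without replicate 1 of those with it.

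Genes of serine synthesis had positive fold changes, Phgdh 1.32 ± 0.48, Psat1 0.57 ± 0.18 and Psph 0.21 ± 0.34. Of these 0 of 3 passed over all genes and 2 adjusted over the list alone (median 0.575, adjusted p = 0.0105, from 0.00334 to adjusted p = 0.483 with an estimated correlation). Shmt2 stood at 0.64 ± 0.28. Cholesterol synthesis genes lay lower, with 4 of 22 past the threshold adjusted over the list alone and 0 over all genes, and Hsd17b7 stood at -0.91 ± 0.23. The list median was -0.227 (adjusted p = 2.24e-05, from 3.53e-12 to adjusted p = 0.483 with an estimated correlation). Il1b, near its floor without LPS, stood at -0.13 ± 0.65, Il1a at -0.14 ± 0.62 and Tnf at 0.26 ± 0.25, and the lists of cytokines, NF-kB genes and interferon-stimulated genes gave adjusted p = 0.886, 0.918 and 0.94. The NF-kB and interferon-stimulated lists had medians of -0.00534 and -0.00657 but means of 0.0607 and 0.0387 and tests toward higher levels. Chemokine genes had a median of 0.287 and passed with the block and not without it (adjusted p = 0.0834 without and 0.0429 with it, from 0.0429 to adjusted p = 0.636 with an estimated correlation). Without the 3 members at the floor, with at most 3 counts over a compared group, they passed neither without the block nor with it (adjusted p = 0.191 and 0.162). The glutathione and NRF2 list, at adjusted p = 0.867 over all libraries with a median of -0.034 and a mean of 0.00333, passed toward lower levels without replicate 4 of the untreated cells without serine (0.00261), and over 6 alternatives it ranged from 3.47e-06 to 0.973. The direction of Il1b and Il1a turned when single libraries were left out. Il1b stood at 0.62 without replicate 1 of the cells with serine and at 0.26 and 0.15 without replicates 2 and 3 of those without. Il1a stood at 0.13 without replicate 1 with serine and at 0.03 and 0.01 without replicates 3 and 4 in its absence. All 26 ribosomal protein genes and 24 of 25 complex I genes had positive fold changes, with medians of 0.616 and 0.542 and Rps24 and Ndufa2 at 1.36 ± 0.51 and 1.73 ± 0.61. Both lists passed (adjusted p = 5.35e-06 and 1.8e-05, and adjusted p = 0.935 for both with an estimated correlation). Without replicate 4 of the untreated cells without serine the tests of both lists turned toward lower levels (adjusted p = 0.185 and 0.159), and Rps24 and Ndufa2 stood at -0.02 and -0.03. With the block and that library left out, the lists of lysosome, macrophage marker and DNA replication genes passed (adjusted p = 0.0102 for each).

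Over all 11004 genes the edgeR test called 0 genes, with 548 at an unadjusted p under 0.05. Every left-out library gave 0 as well, while DESeq2 called 12 higher and 1 lower, edgeR with no filter on low counts 2 higher (Mthfd2 and Cars), and the block without replicate 4 of the untreated cells without serine 70 higher and 9 lower. The authors' deposited table marks 6 genes higher and 0 lower, with Mthfd2 at 1.54 (adjusted p = 0.00125). Its marks reach an adjusted p of 0.00706 at most, and 7 of its genes lie under 0.05.

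Serine withdrawal in LPS-treated cells is the comparison closest to the series title. Il1b averaged 755 ± 130 CPM with serine and 357 ± 64.6 CPM without it, a log2 fold change of -1.08 ± 0.26, lower in 4 of 4 replicate pairs. It missed the threshold over all genes in the unpaired test (edgeR adjusted p = 0.151) and passed it with the replicate block (-1.08 ± 0.18, adjusted p = 0.0137). The unpaired test ignores the pairing of the libraries, and replicate 4 of the untreated cells without serine raises its shared spread. Over 17 alternatives the fold change of Il1b ranged from -1.21 to -0.97 and the adjusted p from 5.23e-29 to 0.492. Il1a averaged 442 ± 125 and 315 ± 109 CPM (-0.49 ± 0.24) and Il6 145 ± 27.9 and 95 ± 27.2 CPM (-0.61 ± 0.21), both lower in 4 of 4 pairs and past the threshold neither with the block over all 16 libraries nor without it. Both passed with the block on the 8 LPS libraries alone (adjusted p = 5.32e-11 and 8.97e-14) and with the block without replicate 4 of the untreated cells without serine (adjusted p = 2.59e-05 and 0.000112). The former fit called 2259 of 9989 genes and the latter 922 of 11107, so a pass there sets a gene less apart. Il1a stood at -0.28 without replicate 1 with serine and LPS and at -0.76 without replicate 1 with LPS and no serine. Replicate 1 was the highest in both groups (621 and 471 CPM), and these unpaired fits kept it on a single side. Tnf averaged 1290 ± 323 and 1200 ± 222 CPM (-0.11 ± 0.23), and stood at 0.08 when replicate 1 with serine was left out of the unpaired test. It passed the threshold under 1 of its 17 alternatives (adjusted p = 0.015). As a list, cytokines were lower, with a median of -0.195, 0 of 17 past the threshold over all genes and 1 adjusted over the list alone (adjusted p = 0.00248, from 0.00106 to adjusted p = 0.226 with an estimated correlation). With the block 1 cytokine fell, and 5 adjusted over the list alone. Several other divisions of the same libraries, given below, gave as small a p for the cytokine list without the block. NF-kB genes had a median of -0.0423 (adjusted p = 0.482) and interferon-stimulated genes one of 0.0479 (adjusted p = 0.797).

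Of 11004 genes 6 rose and 1 fell without serine in LPS-treated cells in the unpaired test. Cxcr4 (chromosome 1, 128588199 to 128592293, minus strand), a chemokine receptor gene, rose by 1.10 ± 0.15 from 45.5 ± 3.54 to 97.8 ± 21.9 CPM (edgeR adjusted p = 0.0181), and the small GTPase gene Arl11 (chromosome 14, 61309753 to 61311936, plus strand) by 1.12 ± 0.16 from 18.1 ± 2.78 to 39.4 ± 10.2 CPM (adjusted p = 0.0199). Pck2 rose by 1.45 ± 0.23, Leprotl1 by 0.54 ± 0.09, the p53-inducible gene Trp53inp1 by 0.83 ± 0.14 and Cebpg, a partner of ATF4, by 0.88 ± 0.15 (adjusted p = 0.0257, 0.0363, 0.0475 and, just under the threshold, 0.05). Emilin1 (chromosome 5, 30913402 to 30921278, plus strand), an extracellular matrix gene, fell by 1.05 on the log2 scale from 42.1 ± 6.45 to 20.3 ± 5.10 CPM (adjusted p = 0.0257). All 7 went the same way in 4 of 4 replicate pairs. Each of the 7 missed the threshold without replicate 2, 3 or 4 with serine and LPS and without replicate 4 with LPS and no serine. Of that last group, Arl11 also missed it without replicate 2, and Pck2 and Emilin1 without replicate 1 or 2. Cebpg missed it without any LPS library but replicate 1 with serine, and Leprotl1 and Trp53inp1 without any of the 8. Over 17 alternatives each, the adjusted p ranged from 6.36e-18 to 0.097 for Cxcr4 and from 2.65e-13 to 0.238 for Leprotl1. With the replicate block 73 genes rose and 25 fell, these 7 among them.

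Groups that were higher without serine held genes of amino acid supply. Of 27 ATF4 targets 2 rose over all genes, 17 adjusted over the list alone and 13 with the block. The list median was 0.881 (adjusted p = 2.52e-23, from 1.27e-26 to adjusted p = 0.0589 with an estimated correlation). Asns averaged 87.3 ± 27.0 CPM with serine and 226 ± 43.7 CPM without it, a log2 fold change of 1.37 ± 0.26. Trib3 averaged 25.5 ± 11.3 and 80.9 ± 32.1 CPM (1.66 ± 0.36) and Chac1 16.3 ± 8.60 and 47.3 ± 13.7 CPM (1.53 ± 0.38). These 3 passed with the block and not without it, as did the amino acid transporter gene Slc7a5 (1.22 ± 0.38) and Aldh18a1 of proline synthesis (1.27 ± 0.39). Of 20 aminoacyl-tRNA synthetases 0 passed over all genes, 13 were higher and 1 lower adjusted over the list alone, and 11 rose with the block. Among the 11 were Mars (0.84 ± 0.16), Cars (0.78 ± 0.18), Nars (0.74 ± 0.16) and Aars (0.78 ± 0.20). Without replicate 1 with serine and LPS, Asns and Nars passed in the unpaired test as well, at 1.58 and 0.91. The synthetase list had a median of 0.659 (adjusted p = 5.12e-15, from 3.89e-17 to adjusted p = 0.0589 with an estimated correlation). Phgdh averaged 9.62 ± 5.13 CPM with serine and 27.4 ± 10.7 CPM without it (1.5 ± 0.44). Psat1 averaged 34.6 ± 0.277 and 62.2 ± 3.81 CPM (0.85 ± 0.17) and Psph 3.35 ± 1.88 and 6.20 ± 2.34 CPM (0.87 ± 0.36). Of these 3 genes of serine synthesis 0 passed over all genes and 3 adjusted over the list alone (median 0.872, adjusted p = 1e-05, from 2.37e-06 to adjusted p = 0.0589 with an estimated correlation). Phgdh and Psat1 passed with the block. Shmt2 (1.17 ± 0.28) and Mthfd2 (0.94 ± 0.25), mitochondrial enzymes of the folate cycle, passed with the block and not without it. The folate list had 2 of 15 higher adjusted over the list alone (adjusted p = 0.126).

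The lists that tested toward lower levels included those of cholesterol synthesis and of glycolysis. Several other divisions of the same libraries, given below, gave as small a p for glycolysis without the block. Cholesterol synthesis genes had a median of -0.421, with 0 of 22 past the threshold over all genes and 1 adjusted over the list alone, or 1 and 11 with the block. Hsd17b7 did not pass at -0.75 ± 0.23 (list adjusted p = 3.32e-08, from 1.42e-08 to adjusted p = 0.138 with an estimated correlation). Glycolysis genes had a median of -0.175, with 0 of 24 past the threshold over all genes and 1 adjusted over the list alone, or 2 and 5 with the block. The lactate exporter gene Slc16a3 (-0.67 ± 0.15) and the enolase gene Eno1 (-0.81 ± 0.26) were the 2 (list adjusted p = 0.00731, from 2.26e-05 to adjusted p = 0.257 with an estimated correlation). Eno1 has a near-identical copy, so its counts are uncertain. The glutathione and NRF2 list stood at a median of -0.115, with 0 of 21 past the threshold in either count, and Srxn1 of this list passed with the block and not without it at -0.48 ± 0.17 (list adjusted p = 0.0106, from 0.00074 to adjusted p = 0.387 with an estimated correlation). Lysosome and autophagy genes had a positive median of 0.107, with 2 of 22 higher adjusted over the list alone and 0 over all genes, led by the folliculin complex genes Flcn (0.74 ± 0.18) and Fnip1 (0.46 ± 0.10). Both passed over all genes with the block and not without it (list adjusted p = 0.00229, from 0.000628 to adjusted p = 0.138 with an estimated correlation). Other genes past the threshold with the block and not without it were the water and glycerol channel gene Aqp9 (1.57 ± 0.33), Klf4 (0.86 ± 0.17) and the pro-apoptotic Bbc3 (0.70 ± 0.16). Among lower genes they included Ch25h (-0.91 ± 0.22), the heat shock gene Hspa2 (-1.09 ± 0.21), the actin-bundling gene Fscn1 (-0.85 ± 0.16), and the chemokine genes Ccl22 (-0.68 ± 0.26) and Cxcl3 (-0.64 ± 0.54, and 0.17 without replicate 1 with serine). With the block the lists of chemokines, macrophage markers and stromal markers passed as well, all toward lower levels (adjusted p = 0.0129, 0.0129 and 0.00106, against 0.0579, 0.116 and 0.13 without it). All 3 missed it at adjusted p = 0.222, 0.222 and 0.242 with an estimated correlation beside the block. With an estimated correlation beside the block, ATF4 targets, synthetases, serine synthesis, cholesterol synthesis, glycolysis, cytokines and lysosome genes passed (adjusted p from 0.00124 to 0.0171). Over 6 alternatives the lists of chemokines, macrophage markers and stromal markers ranged from 0.0129 to 0.389, from 0.0108 to 0.587 and from 0.00106 to 0.729.

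The number of genes called here moved with single libraries. The higher count was 0 without replicate 2, 3 or 4 with serine and LPS or replicate 4 with LPS and no serine, 1 without replicate 2 and 2 without replicate 1 of that last group, and 3 without its replicate 3. It was 2 without replicate 2 or 3 and 3 without replicate 1 or 4 of the untreated cells with serine, 3 without replicate 1 or 2 of those without serine, and 112, with 44 lower, without their replicate 4. The single lower gene was lost without replicates 2, 3 or 4 with serine and LPS, replicates 1, 2 or 4 with LPS and no serine, and replicates 2 or 3 of the untreated cells with serine. With total-count scaling 0 genes passed, DESeq2 called 85 higher and 22 lower, and the test on the 8 LPS libraries alone 24 and 11, or 1208 and 1051 with the block. The block without replicate 4 of the untreated cells without serine gave 553 and 369. The authors' deposited table marks 65 genes higher and 20 lower, with Il1b at -1.08 (adjusted p = 2.91e-08). Its marks reach an adjusted p of 0.00945 at most, and 151 of its genes lie under 0.05.

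**Figure D2:**
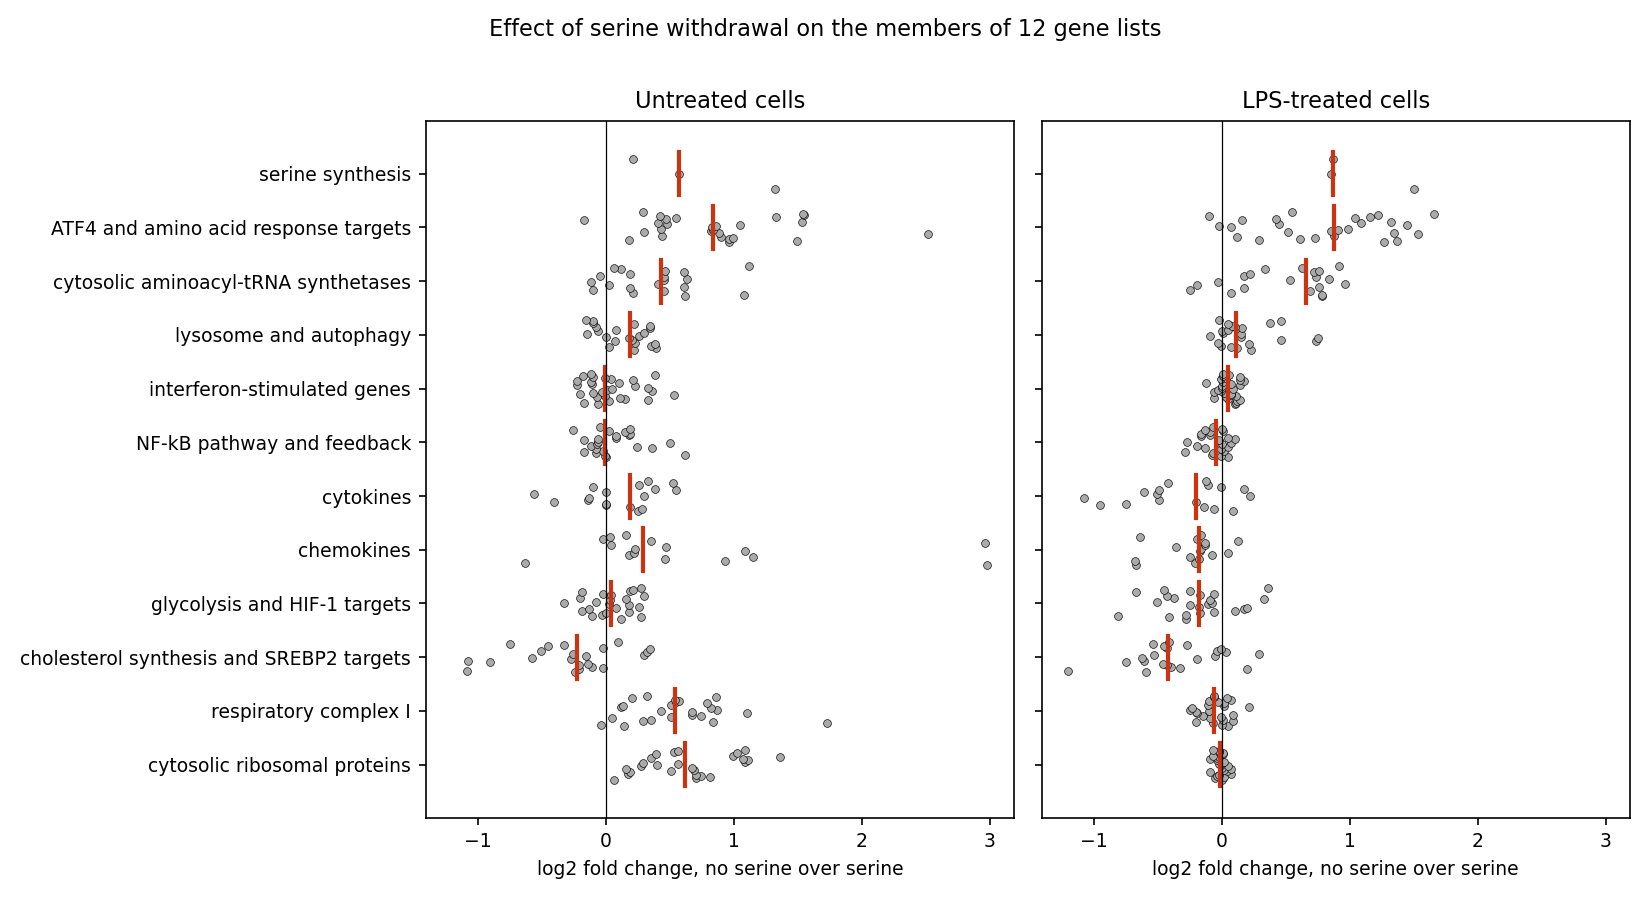
Log2 fold change with serine withdrawal (no serine over serine, horizontal axis) of the members of 12 gene lists (vertical axis) in untreated cells on the left and LPS-treated cells on the right; each point is a gene and each red bar a list median. The medians of ATF4 targets were 0.843 and 0.881, and those of ribosomal protein and complex I genes in untreated cells, 0.616 and 0.542, belong to tests that turned toward lower levels without replicate 4 of the untreated cells without serine.

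The interaction asked whether serine withdrawal acted differently with and without LPS. The difference between the 2 withdrawal effects was -0.95 ± 0.73 for Il1b, -0.35 ± 0.69 for Il1a and -0.37 ± 0.34 for Tnf (edgeR adjusted p = 0.95, 0.963 and 0.95), with Il1b near its floor in untreated cells. For the serine pathway it was 0.18 ± 0.66 for Phgdh, 0.27 ± 0.25 for Psat1, 0.66 ± 0.49 for Psph, 0.53 ± 0.39 for Shmt2 and -0.60 ± 0.35 for Mthfd2, and none of these 8 genes passed. Over 23 alternatives Psat1 ranged from 0.09 to 0.45 and Tnf from -0.56 to -0.13. The sign for Phgdh turned without replicate 2 of the untreated cells with serine (-0.32), replicate 3 of those without it (-0.05), replicate 3 with serine and LPS (-0.08) or replicate 1 with LPS and no serine (-0.03). Il6 gave no usable value, since it had no count in untreated cells. The tests of the chemokine and cytokine lists passed toward lower values (adjusted p = 0.0033 and 0.0141, and adjusted p = 0.809 and 0.912 with an estimated correlation), but they include members at or near 0 counts in untreated cells. Without the 3 chemokines and 4 cytokines with at most 3 counts over a group, medians were -0.318 and -0.337 and neither list passed (adjusted p = 0.062 and 0.315, and 0.912 for both with an estimated correlation). With the block the chemokines passed without those members and the cytokines did not (adjusted p = 0.0156 and 0.183), and with an estimated correlation beside the block neither passed (adjusted p = 0.579 for both). Of the chemokines, Ccl4 averaged 1.48 ± 0.429 CPM with serine and 3.64 ± 2.27 CPM without it in untreated cells and 1140 ± 209 and 955 ± 163 CPM with LPS (-1.40 ± 0.43), and Ccl3 stood at -0.64 ± 0.24. In neither list did a member pass. Ribosomal protein and complex I genes had medians of -0.625 and -0.571 (adjusted p = 0.000907 for both, and adjusted p = 0.912 for both with an estimated correlation). Without replicate 4 of the untreated cells without serine both tests turned toward higher levels (adjusted p = 0.705 and 0.985). The glycolysis list passed with the replicate block and not without it (adjusted p = 0.000354 and 0.0595), and its alternatives ran from 5.4e-06 to adjusted p = 0.912 with an estimated correlation. ATF4 targets, aminoacyl-tRNA synthetases and serine synthesis gave adjusted p = 0.625, 0.315 and 0.315. With the block without replicate 4 of the untreated cells without serine, synthetases, NF-kB genes and stromal markers passed (adjusted p = 0.00993, 0.0103 and 0.00738), the last also without that library and without the block (adjusted p = 0.0184). The ATF4 targets had a median of 0.0348, a test toward higher levels and a mean of -0.0358.

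Cxcr4, chosen after its values were seen, was the only interaction call of DESeq2. It averaged 657 ± 69.9 and 664 ± 79.9 CPM in untreated cells with and without serine against 45.5 ± 3.54 and 97.8 ± 21.9 CPM with LPS, a difference of 1.09 ± 0.21 (edgeR adjusted p = 0.913). Trp53inp1 stood at 0.93 ± 0.19 (adjusted p = 0.95). The edgeR test called 0 of 11004 genes, with 253 at an unadjusted p under 0.05, and 0 with the replicate block, while the block without replicate 4 of the untreated cells without serine gave 4 higher and 4 lower, Cxcr4 and Trp53inp1 among them (1.01 and 0.78, adjusted p = 0.000206 and 0.00802). The direction for Il1b and Il1a turned to 0.16 and 0.25 without replicate 1 of the untreated cells without serine.

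A further comparison asked whether the LPS-responsive genes as a group shifted with serine. Over 1765 genes induced by LPS, chosen by the mean effect in both media, the median centred log2 CPM was 1.02 ± 0.069 in LPS libraries without serine and 1.02 ± 0.085 in those with it, a difference of -3.8e-06 (exact permutation test, two-sided, n = 4 and 4, p = 1). The sign of that difference turned without replicate 1, 3 or 4 with serine (0.017, 0.0149 and 0.00714) and without replicate 2 in its absence (0.0309). In untreated libraries the same genes stood at -1.07 ± 0.285 and -0.984 ± 0.103, a difference of -0.0883 (exact p = 0.857), and 0.0431 without replicate 4 of the cells without serine. Over 1737 genes repressed by LPS the difference was 0.0315 in LPS libraries and -0.0363 in untreated ones (exact p = 0.514 and 0.114), and the former was -0.0155 without replicate 2 with LPS and no serine. With signs exchanged within replicate numbers these differences gave exact p = 0.25 and 0.125, the latter the smallest that 16 arrangements allow. The smallest p that the 70 arrangements allow is 0.0286.

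**Figure D3:**
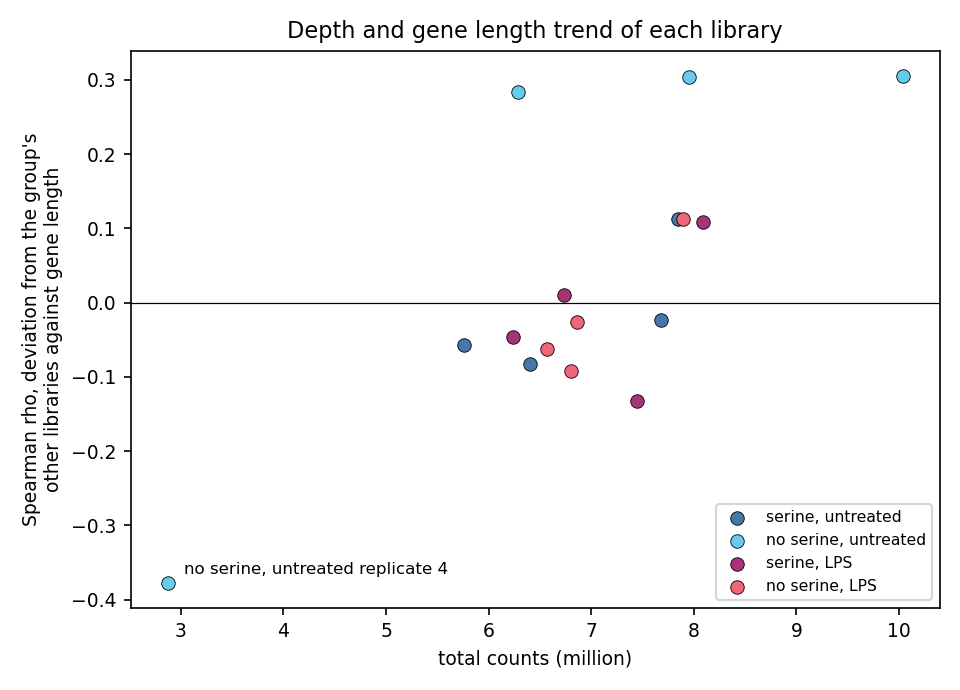
Total counts of each of the 16 libraries (horizontal axis) against the Spearman correlation, across genes, of gene length with the library's deviation from the others of its group (vertical axis); each point is a library, coloured by group, and genes are not independent replicates. Replicate 4 of the untreated cells without serine lies at 2871477 counts and -0.377, the other 3 libraries of its group between 0.283 and 0.305 because they are compared with it, and the remaining 12 between -0.132 and 0.112.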

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

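The tests of a loss of long transcripts, both tests of the ribosomal and complex I genes, the tests of a weaker LPS response and of fewer responding cells, the lists without members at the floor and the counts of splits for single lists were chosen after the result was seen.

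Replicate 4 of the untreated cells without serine stood apart from its group. Its TMM factor of 1.04 lay far from the other 3 (1.24 to 1.27), with a gap to the nearest of 0.87 of the range. It also stood far from the others of its group in log2 CPM of Ndufa2 of complex I (gap of 0.986 of the range), Rps24 of the ribosome (0.938) and the lactate exporter Slc16a3 (0.874). Low depth was argued against: thinned to its total, the other 3 libraries had correlations of deviation with gene length no lower than -0.0646, against -0.377. RNA from LPS-treated cells was argued against, since 7 genes nearly silent without LPS stood at 0.109% of their LPS level in it and at 0.112%, 0.0315% and 0.0598% in the others. So was serine withdrawal itself, whose effect without that library correlated with length at 0.0689. A loss of long transcripts as the whole cause was not decided, because the deposited lengths are of genes, not expressed transcripts. Over 3743 genes of at least 50 CPM, with the others thinned to its total, the SD of its deviation (log2) was 0.942, and 0.824 with the trend with gene length removed, against 0.264 to 0.394 in the others. What set that library apart stays open.

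Ribosomal protein and complex I genes had a median log2 fold change of 0.564 over 51 genes with serine withdrawal in untreated cells. Without replicate 4 of the untreated cells without serine the median was -0.0245 with the replicate block. The positive median therefore depended on that library. In LPS-treated cells the median was -0.0187, which cannot decide on an effect of serine withdrawal limited to untreated cells. In the difference between the withdrawals, complex I and ribosomal protein genes each gave adjusted p = 0.000907, and 0.985 and 0.705 without that library.

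Il1b was lower with serine withdrawal in LPS-treated cells, at -1.08 ± 0.26. A weaker response of every induced gene was argued against by a median of -0.00194 over 1727 LPS-induced genes, whose 5th to 95th percentiles ran from -0.471 to 0.342, with 3 genes at or below Il1b. Fewer responding cells would lower induced genes together, which the same median also argued against. Interferon-stimulated genes had a median of 0.0479 and a range of -0.115 to 0.17. They do not decide it, because secreted interferon can raise them in cells that did not respond to LPS. Bias by gene length, the only length at hand, was argued against by a median of -0.0215 over 545 genes within 10 percent of the length of Il1b. What lowers Il1b stays open, because other technical causes were not tested. The difference missed the threshold in the unpaired test (adjusted p = 0.151) and passed with the replicate block (-1.08 ± 0.18, adjusted p = 0.0137), lower in 4 of 4 pairs.

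In the difference between the withdrawals the lists of cytokines (adjusted p = 0.0141) and chemokines (adjusted p = 0.0033) passed toward lower values, and neither did with an estimated correlation (0.912 and 0.809). Some of their members had 0 to 3 counts over a group of untreated cells, and without these neither list passed (adjusted p = 0.315 and 0.062), so no difference between the withdrawals is drawn from them. With the block chemokines passed without these members (0.0156) and cytokines did not (0.183), and neither passed with the block and an estimated correlation (0.579 for both).

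Single libraries lay far from the others of their group in 8 further gene levels (log2 CPM), each given as the gap to the nearest over the range of the group. With serine and LPS this was Atf4 in replicate 1 (0.831). With LPS and no serine it was Bmf in replicate 2 (0.887), Cebpg in replicate 1 (0.871) and Il12b in replicate 4 (0.975). In untreated cells with serine it was Ccl22 (0.832) and Rps24 (0.84) in replicate 4, and without serine Leprotl1 (0.897) and Nos2 (1) in replicate 3, where Nos2 had the single count of its group. Such gaps were found in 11 of 300 groups of gene levels, 3 of them in replicate 4 of the untreated cells without serine, against 15 expected by chance (about 1 in 20), and in 1 of 20 groups of library values, against 1.

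Each comparison of 2 groups was set against other divisions of the same 8 libraries into groups of 4. With LPS in the presence of serine, 1 of 35 splits, the real one, gave as many genes (6139, highest other 0), and without serine 1 of 35 (6250, highest other 682). For withdrawal with LPS 1 of 35 gave as many genes (7, highest other 0), and 1 of 35 with the replicate block (98, highest other 0). In untreated cells all 35 gave at least the real count of 0 (highest other 1), and 1 of 35 with the block (9, highest other 0). For the difference between the withdrawals 100 of 100 gave at least its count of 0. Replicate numbers pair the libraries, and only 8 splits part all 4 pairs, too few for a share under 0.05. The highest count of the 7 others among these was 0 genes in each comparison of 2 groups.

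Numbers of gene lists were less distinct from other splits. Splits that keep pairs together also hold differences between replicates, and some splits hold part of the real contrast. Their lists therefore do not measure chance alone. As many lists came from 27 of 35 splits for LPS with serine (7, highest other 15), 15 of 35 for LPS without it (8, highest other 13), 20 of 35 for withdrawal in untreated cells (6, highest other 14) and 11 of 35 with LPS (8, highest other 14). With the block these were 6 of 35 (7, highest other 11) and 1 of 35 (11, highest other 10). Among the 7 other splits that part all 4 pairs, the highest was 8 and 9 lists for LPS, and 5 and 7 for the withdrawals or 5 and 9 with the block. The difference gave 84 of 100 (4, highest other 13). For ATF4 targets, 1 of 35 splits gave as small an unadjusted p as the real one in each withdrawal, with 9.46e-21 against a smallest other of 9.34e-14 in untreated cells and 8.41e-25 against 1.59e-21 with LPS. For the other lists that passed without the block the numbers varied. For withdrawal with LPS the numbers of splits were 1 for synthetases, serine synthesis and lysosome, 2 for cholesterol synthesis, 4 for glutathione, 6 for cytokines and 7 for glycolysis, and in untreated cells 1 for synthetases, 2 for serine synthesis, 3 for cholesterol synthesis and 29 each for ribosomal and complex I genes. For LPS with serine they were 19 for ATF4 targets, 15 for DNA replication, 2 for interferon-stimulated genes and 1 for the other 4 lists, and without serine 13, 8 and, for the other 6 lists, 1. In the difference they were 2 of 100 for chemokines, 8 for cytokines and 65 each for ribosomal and complex I genes.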

How the results depend on the processing

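Total-count scaling, the tests that combine the block with another change, the lists without 1 library or without members at the floor, and the removal of libraries of groups not compared were chosen after the result was seen. In this part, the cause of a change was not tested unless a sentence names it.

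Total-count scaling, which lacks the composition factors of TMM, gave 1666 genes higher and 6407 lower for LPS with serine and 1686 and 6566 without it, 0 and 0 for withdrawal with LPS, and opposite signs for Shmt2 (LPS with serine, -0.40) and Psph (LPS without serine, -0.10). It left 125 of 136 named results alike and 9 weaker. No filter on low counts gave 2 genes higher for withdrawal in untreated cells and 3 with LPS. DESeq2 gave 12 higher and 1 lower in untreated cells, 85 and 22 with LPS, and 1 higher in the difference between the withdrawals. The 8 LPS libraries alone gave 24 and 11, and 1208 and 1051 with the block, which called 0 on the 8 untreated libraries alone. RLE size factors kept 135 named results and turned the median shift of induced genes in LPS libraries to 0.00268, and the stricter filter kept all 136.

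The replicate block gave 9 higher genes in untreated cells and 73 higher and 25 lower with LPS. It made 36 of 136 named results and 5 list results pass, each named in its comparison, and changed no other call among named genes and lists. Over all genes it gave 3263 higher and 3379 lower for LPS with serine, and 3237 and 3482 without it. Without replicate 4 of the untreated cells without serine the block gave 70 higher and 9 lower for withdrawal in untreated cells. In the same setting it gave 553 and 369 for withdrawal with LPS, and 4 and 4 in the difference. That library raises the spread that all groups share, with a coefficient of variation of 20.9% with it and 14.1% without it. Under the same setting Ndufa2 in untreated cells stood at -0.05, and list directions turned for ribosomal proteins in LPS without serine (adjusted p = 0.00131), in untreated withdrawal (0.328) and in the difference (0.805), and for complex I in untreated withdrawal (0.202). With the unpaired test and that library left out these were 0.0804, 0.185, 0.705 and 0.159, and complex I in the difference 0.985.

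An estimated correlation left 3 lists past the threshold in each LPS comparison, 0 in both withdrawals and 0 in the difference. With the block it left 4 in each LPS comparison, 2 for untreated withdrawal (ATF4 targets and synthetases), 7 for withdrawal with LPS (these 2, serine synthesis, cholesterol synthesis, glycolysis, cytokines and lysosome) and 0 in the difference. Without members at the floor, 2 lists passed in the difference, and cytokines and chemokines did not (adjusted p = 0.315 and 0.062). With the block and replicate 4 of the untreated cells without serine left out, the ribosomal protein list passed for LPS with serine (adjusted p = 0.00217). The dendritic cell marker list stood at the threshold there (adjusted p = 0.05).

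Leaving out single libraries gave 0 to 112 higher and 0 to 44 lower genes for withdrawal with LPS, the highest without replicate 4 of the untreated cells without serine. These fits are unpaired, so a left-out library leaves its same-numbered partner in the other group, which can shift a fold change. Among named results, 1144 values kept direction and call, 51 became weaker, 2 stronger and 19 turned. The turned ones ranged as follows. With LPS and serine Shmt2 ranged from -0.02 to 0.41 and Psph from -0.46 to 0.02. In untreated withdrawal Ndufa2 ranged from -0.03 to 2.05, Rps24 from -0.02 to 1.64, Il1b from -1.24 to 0.62 and Il1a from -0.74 to 0.13. With LPS, Tnf ranged from -0.25 to 0.08 and Cxcl3 from -1.51 to 0.17. In the difference Il1b ranged from -1.70 to 0.16, Il1a from -0.62 to 0.25 and Phgdh from -0.32 to 0.52. The median shift of induced genes ranged from -0.039 to 0.0309 in LPS libraries and from -0.19 to 0.0431 in untreated ones, and that of repressed genes with LPS from -0.0155 to 0.0757.

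Il1b kept its lower level in LPS-treated cells under all 17 alternatives (-1.21 to -0.97), and its call passed under 5 of them. Depth limits what near-silent genes can show, such as Il1b and Il1a in untreated cells.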

Other observations

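The counts of shared genes in this part were chosen after the result was seen. Genes called higher without serine overlapped between untreated and LPS-treated cells. With the replicate block 9 genes rose in untreated cells and 73 with LPS, and 8 were common to both, against 0.0597 expected if the calls were independent among 11004 genes. Of the 73 genes, 71 (97.3%) had a positive fold change in untreated cells, and of the 25 lower genes 19 (76%) had a negative one. The compared libraries differ between the withdrawals, but the same replicate numbers occur in both, and the same fit with a shared spread per gene gave both. The calls are therefore not independent, and the expected count is not a test. Over all 11004 genes the median log2 fold change in untreated cells was 0.00295 with the block.

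Atf4 itself averaged 151 ± 32.9 and 295 ± 56.4 CPM in untreated cells with and without serine, and 337 ± 80.8 and 513 ± 61.8 CPM with LPS (mean ± SD, n = 4). Trib3 averaged 16.1 ± 4.85 and 47.2 ± 17.6 CPM in untreated cells. Slc16a3 averaged 53.7 ± 5.86 CPM with serine and LPS and 33.7 ± 5.66 CPM with LPS and no serine.

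Replicate 1 of all 4 groups lacked Xist counts and had Y-linked counts, while replicates 2 to 4 of all groups had Xist counts and at most 1 Y-linked count. Replicate 1 was therefore male and replicates 2 to 4 female, so replicate 1 came from another animal than the others. The labels do not say whether the numbers 2 to 4 name separate animals.

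The authors' deposited tables mark 3227 genes higher and 3182 lower with LPS in the presence of serine, and 2213 and 1968 in its absence. Marked genes reach an adjusted p of 0.00999 at most in both, and 7385 and 5372 genes lie under 0.05. Their table for LPS-treated cells gives Psat1 at 0.85, Mthfd2 at 0.93, Phgdh at 1.5 and Shmt2 at 1.17 (adjusted p = 2.91e-08, 2.91e-08, 0.00283 and 0.00289).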
